A study of Mus musculus with 96 samples.

How the data were processed

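Expression was measured in liver and muscle of ob/ob, db/db, lean control and HFD mice of 16 and 48 weeks, non-fasted or fasted, with 3 arrays in each of 16 groups per tissue. The strains were B6.V-Lep ob/J, B6.BKS(D)-Lepr db/J and, for the lean and HFD mice, C57BL/6J, and the diets D12450B (low fat; ob/ob, db/db and lean) and D12492 (high fat). Per the labels' protocols, RNA was isolated with a kit for lipid-rich tissue, checked on a Bioanalyser, labelled with biotin and hybridised to Illumina MouseRef-8 v2.0 bead arrays. Samples were grouped by tissue, model, age and feeding state as the labels give them, and replicate numbers were taken from the labels.

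The deposited data used were, for each tissue, a set of probe signal intensity on a linear scale, not normalized, with a detection p-value for each probe and array, both per the file headers. The scanner software, its settings and any background subtraction before export are not given in the sources used here. A value table for all arrays, deposited by the authors as normalized signal intensity, was used only as an alternative. Its values are on a linear scale, since log2 of them gave the same counts as quantile normalization without background correction. The method of that normalization is not given in the sources used here.

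Each tissue was processed separately with limma 3.58.1 in R 4.3.3, with the data.table package (1.17.8). Background was corrected by normexp with the background estimated from the detection p-values (offset 16), followed by quantile normalization and log2. Probes were kept when detected at p under 0.01 on at least 3 arrays of the tissue. Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 had none; 23962 were given the current symbol through their gene ID, with RefSeq genes of assembly GRCm38.p6, and the rest kept the annotation's name. Probes without a symbol were left out, and the probe with the highest mean value stood for each gene. This left 8250 genes in liver, from 11810 probes, and 8239 in muscle, from 11705. Of 2108 liver genes with several probes, 174 had probes called in opposite directions for ob/ob against lean and 196 for age; in muscle 12 and 28 of 2075 did. The 95th percentile of signal was 19.3 to 36 times the 5th in liver (median 26.4) and 19.3 to 39.7 times in muscle (median 31), which limits how large a fold change can be read.

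A linear model with a mean for each of the 16 groups was fitted per gene, over all 48 arrays of the tissue, and tested with empirical Bayes moderation. Each model was set against lean, averaged over age and feeding state with equal weight, and so were the mean of ob/ob and db/db against HFD, ob/ob against db/db, fasted against non-fasted and 48 against 16 weeks, averaged over all models. Differences in response are the fasting or age change of HFD mice, or of the mean of ob/ob and db/db, minus that of lean mice. P-values were adjusted over the genes of a contrast with Benjamini-Hochberg, and an adjusted p under 0.05 was called. Comparisons that use the same lean arrays share their chance values, and no overlap between them was tested.

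In all, 29 gene lists were fixed before the data were examined, covering metabolic pathways, sex-biased liver genes, stress and matrix genes, fibre types and markers of other cell types. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the arrays. Counts of called members are over all genes, with the count adjusted over the list alone beside it where given. The genes named follow a rule also fixed before: for each contrast the 5 highest and the 5 lowest called genes with the same direction in every stratum averaged, the 3 members of each list with the smallest p, and Lep and Lepr, of which the text takes at most about 30 per contrast. A gene detected in no array of the dimmer arm is given as at least N-fold, from the mean of the brighter arm and, in the dimmer arm, the mean per array of the higher of the lowest detected signal and the probe's own. For genes detected on some arrays of the dimmer arm, folds are given as the same bound, a choice made after the data were seen.

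The model was tested on simulated data with the real groups and spread. For ob/ob against lean it recovered 92.5% of 67 genes changed by 0.5 log2 in liver and 83.6% in muscle. For the fasting response of HFD against lean it recovered 49.3% and 35.8% of 67 genes at 0.5 and 92.5% and 82.1% of 67 at 1 log2. At most 0.125% of unchanged genes were called, which gives no rate for the real arrays.

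Settings fixed before the data were examined, each in place of the one above, were no background correction, normexp without detection p-values (offset 50), median scaling in place of quantile normalization, no filter, detection on 24 of the 48 arrays, the mean of a gene's probes, the submitters' normalized values, array weights, a trended and robust prior, fits of only the groups compared, a replicate block, and leaving out each array in turn. After the data were seen, runs of 8 sample numbers as a random block, steps at sample number 33 (liver) and 17 (muscle) as a fixed factor, the ages separately, ob/ob (liver) and HFD mice (muscle) alone for age, scores of other-tissue transcripts as covariates, and leaving out 7 muscle arrays of wide spread were added. The score lists held kidney, bone marrow, liver and brown fat transcripts and were written after the spread in muscle had been seen. The slide as a block was planned but not run, since the tables name no slide. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.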

Results

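Gene expression was measured with 96 single-colour bead arrays, 48 of liver and 48 of muscle, from 4 mouse models. The ob/ob mice lack leptin and the db/db mice lack its long receptor; both eat in excess (hyperphagic) and were kept on a low-fat diet. Lean controls were C57BL/6J mice on the same low-fat diet, and HFD mice were C57BL/6J on a high-fat diet. Each model was sampled at 16 and 48 weeks of age, non-fasted or fasted, which gave 16 groups of 3 arrays per tissue and 12 arrays per model and tissue. The labels do not state that the 3 replicates of a group are separate animals, and p-values then measure only the spread between these samples, which may be technical.

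The arrays detected 9084 to 10858 of 25697 probes in liver and 8684 to 10691 in muscle. Correlations between replicates of a group were at least 0.973 in liver (median 0.990) and at least 0.941 in muscle (median 0.982), and no 2 arrays held identical signals. Changes are given as the log2 difference ± SE from limma, with adjusted p after Benjamini-Hochberg, and the number of arrays limits their precision. Where only some arrays of the dimmer arm detected a gene, its difference is set partly against background readings, and a fold is given as a bound (at least). Not every such gene has its detection count beside it. Lep, which encodes leptin, was not detected on any liver array. In muscle it was detected in every group, ob/ob included, so its probe reads the ob/ob transcript and does not check that label. The probes of Lepr, the leptin receptor gene, were not detected in either tissue.

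All 16-week and all ob/ob liver arrays have a sample number below 33 in the submitters' numbering, and all 48-week lean and HFD arrays a higher one. Only 1 group, non-fasted 48-week db/db, lay on both sides. Its replicate 3, from number 33 up, differed from replicates 1 and 2 in 984 genes and spread most widely of the liver arrays (SD around group means 0.305). The error in that test comes from the other groups, so a single aberrant array would give such a count too. A fixed factor for it (the step at 33) is estimated from this 1 array alone, which also widens the error of the comparisons it enters. In muscle the 95th percentile of signal was 19.3 to 26.8 times the 5th on arrays 1 to 16 and 26.3 to 39.7 times on arrays 17 to 48. All 16-week ob/ob and db/db, all non-fasted 16-week lean arrays and 1 fasted one lie below number 17, and all HFD and 48-week arrays above. A fixed factor for this (the step at 17) again rests on that 1 array and widens the error; it called 2 genes itself. Within runs of 8 the consensus correlation was 0.135 in liver and −0.0489 in muscle, where it shows no run effect and can add calls. Muscle arrays also differed within groups in kidney, liver and bone marrow transcripts, and 7 spread widely around group means. Counts allowing for these features, all chosen after the data were seen, stand beside those they moved by more than 1.5 times.

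**Figure D1:**
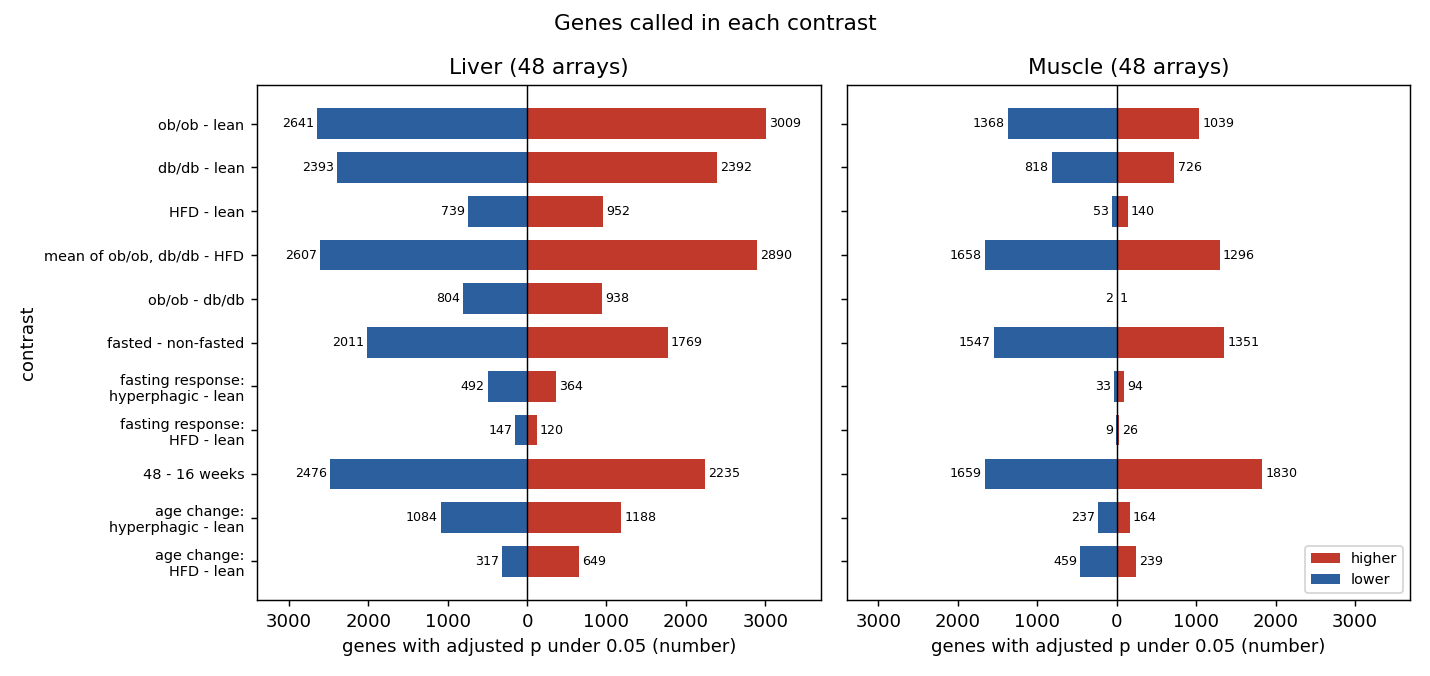
Number of genes called at an adjusted p under 0.05 in each comparison, higher and lower shown as separate bars, for liver (8250 genes tested) and muscle (8239 genes tested). Liver had 5650 calls for ob/ob against lean, muscle 2407.

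The livers of ob/ob mice differed from lean livers by a loss of male-predominant transcripts and a gain of female-predominant, lipid droplet and matrix transcripts, though these 3 lists lost their calls with an estimated correlation (adjusted p = 0.175 each). Hsd3b5, a male-specific hydroxysteroid dehydrogenase, was at least 29.7-fold lower in ob/ob (adjusted p = 4.61e-21). Cyp7b1, an oxysterol hydroxylase with higher levels in males, fell by 4.15 ± 0.15 (17.8-fold, adjusted p = 3.24e-22). Cyp2b9, a cytochrome P450 with higher levels in females, was at least 26.7-fold higher (detected on 7 of 12 lean arrays; adjusted p = 1.21e-17), and Gpnmb, a glycoprotein of lipid-laden macrophages, at least 14.4-fold (5 of 12). In all, 5650 of 8250 genes differed, 3009 higher and 2641 lower, and 580 of them by at least 2-fold. With median scaling the split was 3402 higher and 1920 lower, and with the step at 33 the count was 3067.

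The other genes at the ends of the ob/ob comparison were Sdcbp2 (at least 13.1-fold, detected on 2 of 12 lean arrays), Cyp2b23 (at least 12.9-fold, 4 of 12) and Ly6d (4.18 ± 0.21) among those higher. Elovl3, a fatty acid elongase, was at least 18.5-fold lower, and Serpina1e (−5.17 ± 0.39) and Cyp4a12b (−4.10 ± 0.28) also fell. Of 13 measured male-predominant liver genes, 0 rose and 13 fell (camera adjusted p = 2.36e-10, and 0.0392 with an estimated correlation). Of 5 female-predominant genes, 4 rose, among them Cyp2b13 (at least 5.78-fold, detected on 2 of 12 lean arrays) and the peroxisomal transporter gene Abcd2 (1.25 ± 0.16, 9 of 12). The camera adjusted p was 0.0197, and the adjusted p = 0.175 with an estimated correlation.

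Lipid storage genes rose in ob/ob liver. Of 17 measured lipid droplet and lipid uptake genes, 12 rose and 2 fell (camera adjusted p = 0.000268, adjusted p = 0.175 with an estimated correlation). Cidea, which promotes droplet growth, rose at least 10.2-fold (3.62 ± 0.20, detected on 9 of 12 lean arrays), the droplet coat gene Plin4 by 2.75 ± 0.15 and the lipoprotein receptor gene Vldlr by 2.51 ± 0.15. Of 17 collagen and stellate cell genes, 16 rose and 0 fell (camera adjusted p = 3.21e-05, adjusted p = 0.175 with an estimated correlation). The collagenase Mmp13 and its inhibitor Timp1, each detected on 1 of 12 lean arrays, were at least 2.76-fold and 1.85-fold higher, and Col4a1 was at 1.05 ± 0.08. Of 15 macrophage markers, 11 rose and 2 fell (11 and 3 over the list alone; camera adjusted p = 0.0197, adjusted p = 0.547 with an estimated correlation). They included Lgals3 (2.34 ± 0.14) and Trem2 (at least 2.99-fold, detected on 5 of 12 lean arrays). Of 12 glycolysis and glucose uptake genes, 7 rose and 0 fell (camera adjusted p = 0.0197, adjusted p = 0.175 with an estimated correlation), led by the hexokinase Hk2 at 2.07 ± 0.11.

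Of 14 insulin and growth hormone axis genes in ob/ob liver, 3 rose and 10 fell (camera adjusted p = 0.0439, adjusted p = 0.175 with an estimated correlation). Igfbp2 fell at least 11.1-fold (−3.49 ± 0.20, detected on 11 of 12 ob/ob arrays), as did Igfals (−1.29 ± 0.09) and Igf1 (−0.80 ± 0.06). Of 13 endoplasmic reticulum stress genes, 2 rose and 9 fell, among them the chaperone gene Hspa5 (−1.59 ± 0.13), with a camera adjusted p of 0.0197 and an adjusted p = 0.407 with an estimated correlation. Cholesterol synthesis (10 of 18 lower), bile acid synthesis and transport (9 of 18 lower; Abcb11 −1.19 ± 0.08) and gluconeogenesis with amino acid breakdown (9 of 18 lower; Pck1 −1.48 ± 0.16) had camera adjusted p of 0.0308, 0.0439 and 0.0308, and adjusted p = 0.579, 0.392 and 0.437 with an estimated correlation. Xenobiotic genes moved apart: 11 of 15 rose and 4 fell, Gsta1 at 3.56 ± 0.22 and Cyp1a2 at −2.01 ± 0.12 (camera adjusted p = 0.043, adjusted p = 0.452 with an estimated correlation). Of 5 oncofetal genes 4 rose, Spink1 among them (2.08 ± 0.20; camera adjusted p = 0.0308, adjusted p = 0.175 with an estimated correlation). Of 20 lipogenesis genes, 11 rose, including the carboxylase Acaca (0.76 ± 0.14), and 1 fell, the transcription factor gene Mlxipl (−0.55 ± 0.08), while the list as a whole did not pass (camera adjusted p = 0.224). Acaca was not called with the step at 33 (0.17) or in 48-week mice alone (0.53).

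In db/db livers Cyp2b9 was at least 26.4-fold and Gpnmb at least 11.5-fold higher. Hsd3b5, detected on 3 of 12 db/db arrays, was at least 25.6-fold lower (adjusted p = 9.3e-20) and Elovl3, detected on 4 of 12, at least 16.6-fold. Lower too were Cyp7b1 (−3.77 ± 0.15, 13.6-fold) and the sulfotransferase gene Sult2a8 (−3.37 ± 0.17, 10.4-fold). Of 13 male-predominant genes, 0 rose and 12 fell (camera adjusted p = 3.12e-12, and 0.0172 with an estimated correlation), and all 5 female-predominant genes rose (camera adjusted p = 0.000685, adjusted p = 0.057 with an estimated correlation). Of 17 lipid droplet genes, 13 rose and 2 fell (camera adjusted p = 2.75e-06, adjusted p = 0.0829 with an estimated correlation). Cidea was at 3.72 ± 0.20. In all, 4785 genes differed from lean, 2392 higher and 2393 lower.

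Of 17 collagen genes in db/db liver, 12 rose and 0 fell (camera adjusted p = 0.000162, adjusted p = 0.224 with an estimated correlation). The macrophage elastase gene Mmp12 was at least 2.78-fold higher (detected on 3 of 12 lean arrays). Of 15 xenobiotic genes 11 rose and 2 fell (camera adjusted p = 0.00062, adjusted p = 0.192 with an estimated correlation; Gsta1 3.72 ± 0.22). Of 18 cholesterol genes 2 rose and 13 fell (2 and 14 over the list alone; camera adjusted p = 0.00227, adjusted p = 0.475 with an estimated correlation). Glycolysis (7 of 12 higher; Hk2 1.64 ± 0.11), macrophage markers (7 of 15 higher and 1 lower; Lgals3 2.16 ± 0.14) and oncofetal genes (3 of 5 higher) passed at camera adjusted p of 0.00857, 0.0141 and 0.0154, with adjusted p = 0.113, 0.475 and 0.0829 with an estimated correlation. Igfbp2 fell by 2.87 ± 0.20 and the stress factor gene Atf3 was at least 2.39-fold higher (detected on 1 of 12 lean arrays), though the insulin and growth hormone list (adjusted p = 0.0767) and the endoplasmic reticulum stress list (adjusted p = 0.0995) did not pass.

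High-fat feeding changed fewer liver genes. Matrix genes rose: of 17 collagen and stellate cell genes, 14 rose and 0 fell (camera adjusted p = 4.19e-11, adjusted p = 0.0895 with an estimated correlation). Timp1 (0.97 ± 0.13) and Mmp13 (0.82 ± 0.12) were each detected on 6 of 12 HFD and 1 of 12 lean arrays, and Col6a1 was at 0.74 ± 0.11. Amino acid breakdown and glucose production genes fell in 11 of 18 cases and rose in 0 (camera adjusted p = 6.63e-07, adjusted p = 0.0895 with an estimated correlation). They included Cps1 (−0.74 ± 0.07) and Got1 (−1.14 ± 0.16). Lipogenesis genes fell in 9 of 20 cases and rose in 0 (0 and 10 over the list alone; camera adjusted p = 0.000635, adjusted p = 0.52 with an estimated correlation). The desaturase Scd1 was at −0.54 ± 0.08, malic enzyme Me1 at −0.68 ± 0.15 and Acaca at −0.60 ± 0.14. In all, 1691 genes differed from lean, 952 higher and 739 lower, 41 of them by at least 2-fold. Median scaling gave 1522 higher and 255 lower, and the 16-week mice alone gave 652 genes. At 16 weeks alone Timp1 (0.12), Mmp13 (0.17) and Col6a1 (0.01) were not called, and at 48 weeks alone Scd1 (−0.12), Me1 (−0.39) and Acaca (−0.42) were not.

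Cyp2b9 rose at least 3.07-fold on the high-fat diet (2.04 ± 0.29, adjusted p = 2.99e-06; detected on 7 of 12 lean arrays), Ubd at least 3.41-fold (1.89 ± 0.19; 8 of 12), and Dbp, a clock output gene, by 1.76 ± 0.27. Cyp4a12b fell 4.17-fold (−2.06 ± 0.28) and Igfbp1 changed by −1.94 ± 0.29. Irs2, an insulin receptor substrate, fell by 1.22 ± 0.17. Of 17 lipid droplet genes, 8 rose and 0 fell (8 and 2 over the list alone; camera adjusted p = 0.000635, adjusted p = 0.356 with an estimated correlation). Plin4 was at 1.06 ± 0.15 and its regulator Pparg at 0.86 ± 0.13. Of 15 macrophage markers, 5 rose (camera adjusted p = 0.00376, adjusted p = 0.579 with an estimated correlation; Lgals3 0.73 ± 0.14). In 16-week mice alone Lgals3 was at −0.07, and Plin4 (0.47) and Cyp4a12b (−0.57) were not called. The cell cycle and oncofetal lists were higher and the oxidative phosphorylation list lower, each at a camera adjusted p of 0.0431, with adjusted p = 0.579, 0.22 and 0.579 with an estimated correlation. The male-predominant list, with 3 genes higher and 4 lower, did not pass (adjusted p = 0.326).

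Set directly against HFD livers, the ob/ob and db/db livers together had lower male-predominant transcripts. Hsd3b5, detected on 3 of 24 hyperphagic and 7 of 12 HFD arrays, was at least 9.89-fold lower (adjusted p = 1.58e-18) and Cyp7b1 12.6-fold lower (−3.66 ± 0.13), and of 13 male-predominant genes 0 rose and 12 fell (camera adjusted p = 7.02e-11, and 0.031 with an estimated correlation). Tceal5 was at least 5.63-fold higher (detected on 3 of 12 HFD arrays; adjusted p = 3.89e-22), Cbr3 at least 8.06-fold (3.19 ± 0.13; 7 of 12) and Cd63 higher by 3.08 ± 0.14. Of 20 lipogenesis genes, 14 rose and 1 fell (camera adjusted p = 0.00585, adjusted p = 0.441 with an estimated correlation). Acaca was at 1.24 ± 0.12 and Scd1 at 0.79 ± 0.07. Of 18 cholesterol genes, 0 rose and 12 fell (camera adjusted p = 0.00213, adjusted p = 0.441 with an estimated correlation). They included Msmo1 (−1.43 ± 0.12). In all 5497 genes differed, 2890 higher and 2607 lower, and 3512 with the step at 33. In 48-week mice alone Hsd3b5 was at −0.14 and not called.

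Other lists separated hyperphagic from HFD livers. Of 17 lipid droplet genes 11 were higher and 2 lower (camera adjusted p = 0.00353, adjusted p = 0.412 with an estimated correlation; Vldlr 2.15 ± 0.13). Of 19 fatty acid oxidation and ketogenesis genes 11 were higher and 2 lower (camera adjusted p = 0.0441, adjusted p = 0.593 with an estimated correlation). Cyp4a14 was at 1.75 ± 0.17 and the hormone gene Fgf21 at 1.43 ± 0.16. Of 13 endoplasmic reticulum stress genes 3 were higher and 8 lower (camera adjusted p = 0.0189, adjusted p = 0.441 with an estimated correlation; Hsp90b1 −1.16 ± 0.08). All 5 female-predominant genes were higher (camera adjusted p = 0.00512, adjusted p = 0.145 with an estimated correlation). Cyp17a1 was at 2.01 ± 0.18. Glycolysis (10 of 12 higher, 1 lower) and xenobiotic genes (10 of 15 higher, 4 lower) had camera adjusted p of 0.0189 and 0.0418, and adjusted p = 0.292 and 0.441 with an estimated correlation. The collagen list, 7 higher and 2 lower of 17, did not pass (adjusted p = 0.186).

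Between the 2 hyperphagic models, ob/ob livers held less of some major urinary protein transcripts than db/db. Mup2 was 3.49-fold lower in ob/ob (−1.80 ± 0.37, adjusted p = 0.000481), and so were Mup6 (−1.58 ± 0.29) and Mup5 (−1.13 ± 0.23), and Cap1 differed by −1.13 ± 0.11 (adjusted p = 5.27e-09). Collagen genes were higher in 8 of 17 cases (camera adjusted p = 0.00586; Mmp2 0.80 ± 0.13), and male-predominant genes lower in 5 of 13 and higher in 1 (camera adjusted p = 0.00586; Keg1 −0.67 ± 0.14). Endoplasmic reticulum stress genes were lower in 4 of 13 (camera adjusted p = 0.000764; Hspa5 −0.66 ± 0.13) and xenobiotic genes in 6 of 15 (camera adjusted p = 0.00266). All 4 lists had an adjusted p = 0.585 with an estimated correlation. The total was 1742 genes, 938 higher and 804 lower in ob/ob (1409 and 511 with median scaling), but 101 in 16-week mice alone, 896 with runs of 8 numbers as a block, and 75 with the step at 33. Mup2, Mup6, Mup5, Keg1 and Hspa5 were not called in 16-week mice alone (−1.01, −0.77, −0.45, −0.31 and −0.40) or with the step at 33 (−0.97, −0.91, −0.32, −0.68 and −0.26).

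Fasting, averaged over the 4 models and both ages, lowered sterol and fat synthesis transcripts in liver and raised those of fatty acid oxidation. All 18 measured cholesterol genes fell (camera adjusted p = 4.02e-22, and 0.0295 with an estimated correlation), led by Mvd, the mevalonate decarboxylase gene, at least 5.49-fold lower (−2.64 ± 0.13, adjusted p = 4.52e-19; detected on 13 of 24 fasted arrays), and Sqle (−2.34 ± 0.13). Of 20 lipogenesis genes, 1 rose and 17 fell (camera adjusted p = 3.92e-13, and 0.0295 with an estimated correlation). Acly was 5.09-fold lower (−2.35 ± 0.10) and the regulator Srebf1 was at −1.96 ± 0.09. Of 19 fatty acid oxidation genes, 17 rose and 1 fell (18 and 1 over the list alone; camera adjusted p = 2.55e-12, and 0.0295 with an estimated correlation). Among them were Cpt1b (1.33 ± 0.08) and Acadm (0.53 ± 0.04). Acot3, an acyl-CoA thioesterase gene, rose at least 5.45-fold (2.51 ± 0.20, detected on 22 of 24 non-fasted arrays) and Cyp4a31 5.33-fold (2.41 ± 0.12, adjusted p = 3.89e-18). In all 3780 genes differed, 1769 higher and 2011 lower in fasted mice, and 2274 in 48-week mice alone.

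Of 17 lipid droplet genes, 14 rose and 1 fell with fasting (camera adjusted p = 1.29e-08, and 0.0295 with an estimated correlation). They included Plin5 (0.93 ± 0.06) and Cidec (1.49 ± 0.13). Gluconeogenesis and amino acid breakdown genes rose in 13 of 18 cases and fell in 2 (camera adjusted p = 0.000378, adjusted p = 0.184 with an estimated correlation; Pcx 0.35 ± 0.04). Of 12 cell cycle genes 0 rose and 10 fell (camera adjusted p = 0.00135, adjusted p = 0.187 with an estimated correlation; Mcm5 −1.01 ± 0.10). Clock genes (8 of 13 higher, 1 lower; Tef 0.84 ± 0.08), atrophy genes (10 of 14 higher, 2 lower; the metallothionein gene Mt1 1.60 ± 0.24), bile acid genes (9 of 18 higher, 4 lower) and male-predominant genes (2 of 13 higher, 8 lower) had camera adjusted p of 0.00714, 0.00408, 0.0223 and 0.0169, and adjusted p = 0.141, 0.187, 0.227 and 0.371 with an estimated correlation.

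The fasting response of the liver differed between hyperphagic and lean mice. Thrsp, a lipogenic nuclear protein gene, had a mean log2 intensity of 12.55 in non-fasted and 7.86 in fasted lean mice at 16 weeks, against 11.98 and 11.00 in ob/ob, and the difference in response was 3.10 ± 0.38 (adjusted p = 1.72e-06). Of 20 lipogenesis genes, 9 had a higher and 1 a lower response in hyperphagic mice (11 and 1 over the list alone; camera adjusted p = 8.09e-06, adjusted p = 0.217 with an estimated correlation; Srebf1 1.26 ± 0.22, Dgat2 0.70 ± 0.10). Of 19 fatty acid oxidation genes, 0 had a higher and 7 a lower response (0 and 12 over the list alone; camera adjusted p = 5.77e-07, adjusted p = 0.152 with an estimated correlation). They included Cyp4a14 (−2.09 ± 0.34), Ppara (−0.75 ± 0.15) and Acadm (−0.55 ± 0.09). Ddit3, a stress-induced transcription factor gene, went from 7.48 to 6.82 in lean and from 6.79 to 8.42 in ob/ob mice at 16 weeks (difference in response 2.17 ± 0.33), and 4 of 13 endoplasmic reticulum stress genes had a higher response (7 over the list alone; camera adjusted p = 2.12e-06, adjusted p = 0.152 with an estimated correlation; Atf4 0.78 ± 0.12). The count was 856, 364 higher and 492 lower, and with median scaling 1339, 108 higher and 1231 lower. It was 423 at 16 and 141 at 48 weeks alone. At 48 weeks alone Cyp4a14 (−0.70), Acadm (−0.41), Srebf1 (0.29), Dgat2 (0.52) and Nsdhl (1.06) were not called. At 16 weeks alone Ppara (−0.74) was not.

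Cholesterol genes (6 of 18 with a higher response; Nsdhl 1.32 ± 0.26), clock genes (3 of 13) and bile acid genes (3 of 18 with a lower response) had camera adjusted p of 9.54e-05, 0.00332 and 0.00258, and adjusted p = 0.507, 0.152 and 0.152 with an estimated correlation. The male-predominant list had a camera adjusted p of 0.0181 in the upward direction (adjusted p = 0.507 with an estimated correlation), but its median turned to −0.0466 with median scaling. Fos (2.70 ± 0.50) and the fatty acid binding protein gene Fabp5 (2.58 ± 0.34) had higher responses and Cidec (−2.04 ± 0.32) a lower one. At 48 weeks alone Cidec was at −0.54 and not called. For these and other genes with a group below detection, a difference of responses rests partly on background readings and is no exact fold.

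In HFD mice the fasting response of gluconeogenesis and amino acid genes was lower than in lean mice. Pck1, which encodes the cytosolic carboxykinase of glucose production, went from 7.95 to 9.07 (16 weeks) and from 7.56 to 9.84 (48 weeks) in lean livers, and from 7.96 to 7.80 and from 7.93 to 7.60 in HFD livers, a difference in response of −1.95 ± 0.33 (adjusted p = 0.000344). Of 18 genes in its list, 0 had a higher and 6 a lower response (0 and 10 over the list alone; camera adjusted p = 3.89e-11, and 0.0185 with an estimated correlation), Ass1 at −1.03 ± 0.18 and Arg1 at −0.53 ± 0.10 among them. Aacs, which activates acetoacetate for lipid synthesis, went from 11.32 to 7.54 in lean and from 10.50 to 9.75 in HFD mice at 16 weeks (difference 2.69 ± 0.25, adjusted p = 8.45e-09). Of 20 lipogenesis genes 7 had a higher and 0 a lower response (12 and 1 over the list alone; camera adjusted p = 1.91e-06, adjusted p = 0.271 with an estimated correlation; Mlxipl 0.91 ± 0.16). Pklr, which is not in that list, also had a higher response (2.14 ± 0.28).

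Fatty acid oxidation (2 of 19 with a lower response), endoplasmic reticulum stress (1 of 13 higher), cholesterol (0 of 18), lipid droplet (2 of 17 lower; Cidec −2.26 ± 0.37) and atrophy lists (0 of 14) also differed between HFD and lean mice at camera adjusted p of 0.000575, 0.000121, 0.00139, 0.0393 and 0.0104, with adjusted p = 0.532, 0.271, 0.66, 0.66 and 0.437 with an estimated correlation. The male-predominant list (3 of 13 higher, Nudt7 1.06 ± 0.12; camera adjusted p = 0.032, adjusted p = 0.66 with an estimated correlation) had a median of −0.115 with median scaling. The count of 267 genes (120 higher, 147 lower) was 128 with median scaling (38 and 90), 406 with array weights, 151 with only the groups compared, 99 at 16 weeks and 21 at 48 weeks, and 162 and 176 without either of 2 lean arrays. Pck1 (−1.28) was not called in 16-week mice alone, Arg1 (−0.11), Mlxipl (0.85), Pklr (1.59) and Cidec (−1.74) were not in 48-week mice alone, and Ass1 was called at neither age (−0.80 and −1.26).

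Age, averaged over the models, lowered male-predominant transcripts in liver: 11 of 13 fell and 0 rose (camera adjusted p = 1.77e-05, adjusted p = 0.212 with an estimated correlation) and Hsd3b5 fell by 2.13 ± 0.17 (detected on 12 of 24 arrays at 16 and 10 of 24 at 48 weeks). All 5 female-predominant genes rose (camera adjusted p = 0.00742, adjusted p = 0.212 with an estimated correlation; Cyp2b9 1.97 ± 0.20). Of 17 collagen genes, 10 rose and 2 fell (camera adjusted p = 0.00521, adjusted p = 0.748 with an estimated correlation). Col3a1 was at 0.88 ± 0.08 and Lum at 0.89 ± 0.08. Tmem45b rose at least 2.33-fold (adjusted p = 1.18e-19) and Tspan8 at least 2.13-fold. Col3a1, Tmem45b and Tspan8 were detected on 1, 2 and 6 of 24 arrays at 16 weeks. The albumin gene Alb fell by 1.03 ± 0.11. The count of 4711 genes (2235 higher, 2476 lower; 2350 and 1601 with median scaling) fell to 2892 with runs of 8 numbers as a block and to 592 with the step at 33, and was 2007 in ob/ob mice alone, which all lie below the step. In ob/ob mice alone Cyp2b9 (−0.23) and Col3a1 (−0.13) changed in the opposite direction and Hsd3b5 was at −0.06. With the step at 33, Cyp2b9 (1.83), Col3a1 (0.39), Lum (0.71), Tspan8 (0.78) and Alb (−1.03) were not called.

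The HFD livers aged differently from the lean livers. At 16 weeks their Gpnmb level was 4.84 ± 0.28 (mean log2 intensity ± SD, n = 6), detected on 0 of 6 arrays, and at 48 weeks 9.30 ± 0.35, detected on all 6, while lean livers went from 5.22 to 6.76. Hsd3b5 was at 12.82 ± 0.26 in 16-week HFD livers and at 5.35 ± 0.69 at 48 weeks, where 1 of 6 arrays detected it, against 11.44 and 9.69 in lean livers (difference in age response −5.73 ± 0.48, adjusted p = 2.47e-10). Cyp4a12b, detected in all groups, differed by −2.99 ± 0.56. Of 17 collagen genes, 13 had a higher and 0 a lower age response on the high-fat diet (15 and 0 over the list alone; camera adjusted p = 9.1e-17, and 0.0164 with an estimated correlation). Lum was at 2.01 ± 0.24, Timp1 at 1.70 ± 0.26 and Col4a1 at 1.05 ± 0.16. The count was 966 genes, 649 higher and 317 lower (999 and 89 with median scaling), and 515 with runs of 8 numbers as a block.

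**Figure D2:**
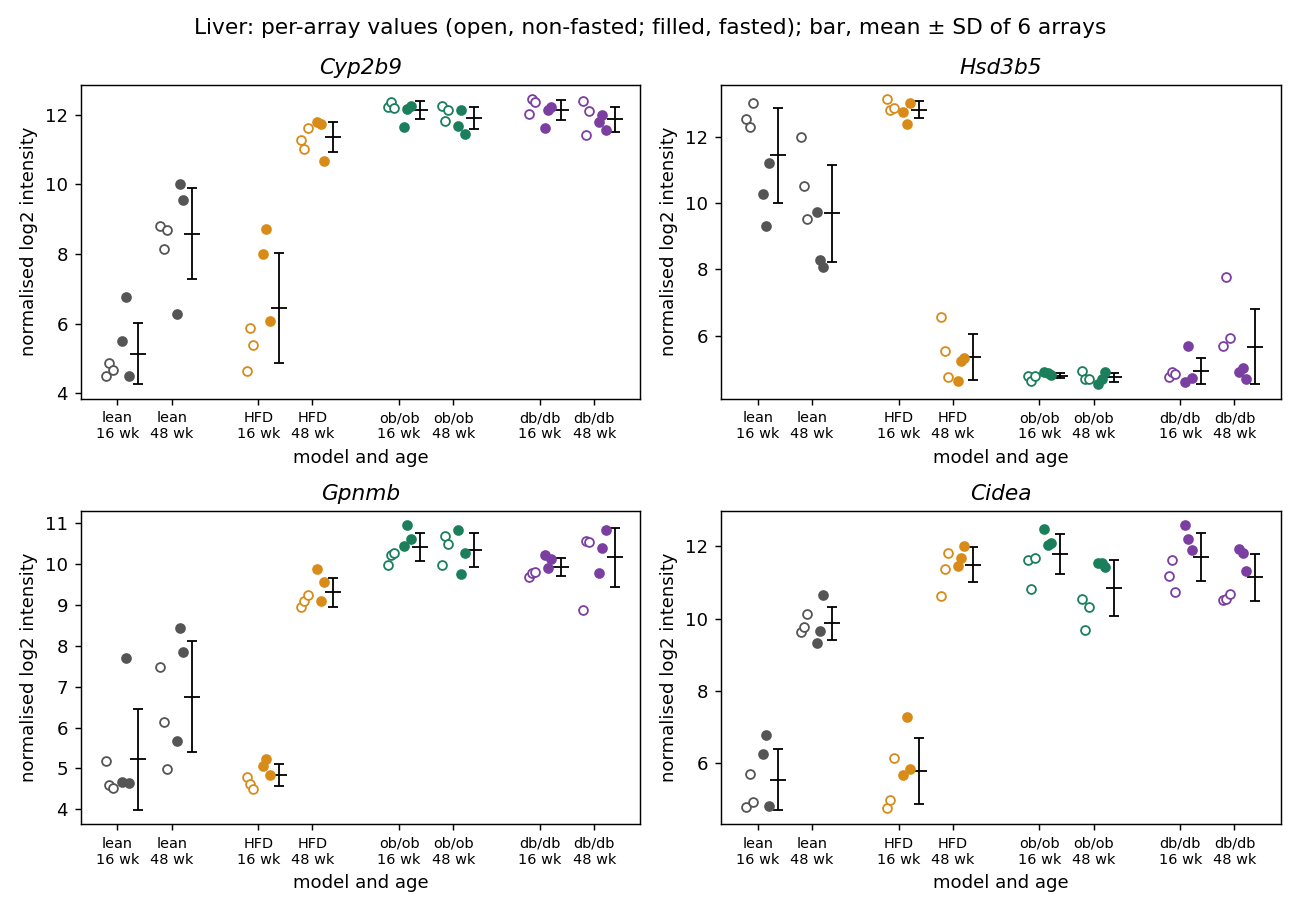
Normalised log2 intensity of Cyp2b9, Hsd3b5, Gpnmb and Cidea on each liver array by model and age, open circles non-fasted and filled circles fasted, with bars for the mean ± SD of the 6 arrays. HFD livers had a mean Cidea level of 5.78 at 16 weeks and 11.49 at 48 weeks.

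Of 18 cholesterol genes, 14 had a lower age response in HFD than in lean livers (17 over the list alone; camera adjusted p = 4.35e-15, and 0.0491 with an estimated correlation). They included Msmo1 (−1.74 ± 0.29) and Idi1 (−1.64 ± 0.27). Male-predominant genes had a lower response in 7 of 13 cases (camera adjusted p = 1.91e-07, and 0.0491 with an estimated correlation; Elovl3 −2.07 ± 0.37). Glycolysis genes had a higher response in 4 of 12 cases (7 over the list alone; camera adjusted p = 4.24e-05, and 0.0168 with an estimated correlation). Hk2 was at 1.88 ± 0.21. Of 15 macrophage markers 7 had a higher and 1 a lower response (10 and 1 over the list alone; camera adjusted p = 6.13e-06, adjusted p = 0.208 with an estimated correlation; Lgals3 1.60 ± 0.27, Trem2 1.34 ± 0.28). Bile acid genes (3 of 18 lower; Slc10a1 −1.13 ± 0.19), female-predominant genes (1 of 5 higher, Cyp2b13 2.42 ± 0.47), endothelial markers (2 of 10 higher; Lyve1 1.29 ± 0.30), lymphocyte markers (0 of 5) and xenobiotic genes (5 of 15 higher, 2 lower) had camera adjusted p of 0.00744, 0.035, 0.035, 0.035 and 0.0407, and adjusted p = 0.165, 0.194, 0.165, 0.228 and 0.431 with an estimated correlation.

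In hyperphagic livers the age response of lipid droplet, xenobiotic and oxidative phosphorylation genes was lower than in lean livers. Cidea differed by −5.09 ± 0.35 (adjusted p = 8.2e-13), and 9 of 17 lipid droplet genes had a lower and 0 a higher response (camera adjusted p = 1.75e-08, and 0.0363 with an estimated correlation; Mogat1 −2.64 ± 0.22). Of 15 xenobiotic genes, 1 had a higher and 11 a lower response (camera adjusted p = 6.24e-08, and 0.0363 with an estimated correlation). Gsta2 differed by −3.06 ± 0.28. Of 26 oxidative phosphorylation genes, 0 had a higher and 17 a lower response (camera adjusted p = 7.83e-09, and 0.0222 with an estimated correlation), Ndufb9 at −1.53 ± 0.21 and Atp5a1 at −1.26 ± 0.22. Insulin and growth hormone genes had a higher response in 5 of 14 cases (Igf1 0.71 ± 0.11) and fatty acid oxidation genes a lower one in 4 of 19, at camera adjusted p of 0.0232 and 0.0282, with adjusted p = 0.0856 and 0.728 with an estimated correlation. The count of 2272 genes (1188 higher, 1084 lower; 502 and 1132 with median scaling) was 1124 with runs of 8 numbers as a block and 150 with the step at 33, where Ndufb9 (−0.39) and Atp5a1 (−0.26) were not called.

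**Figure D3:**
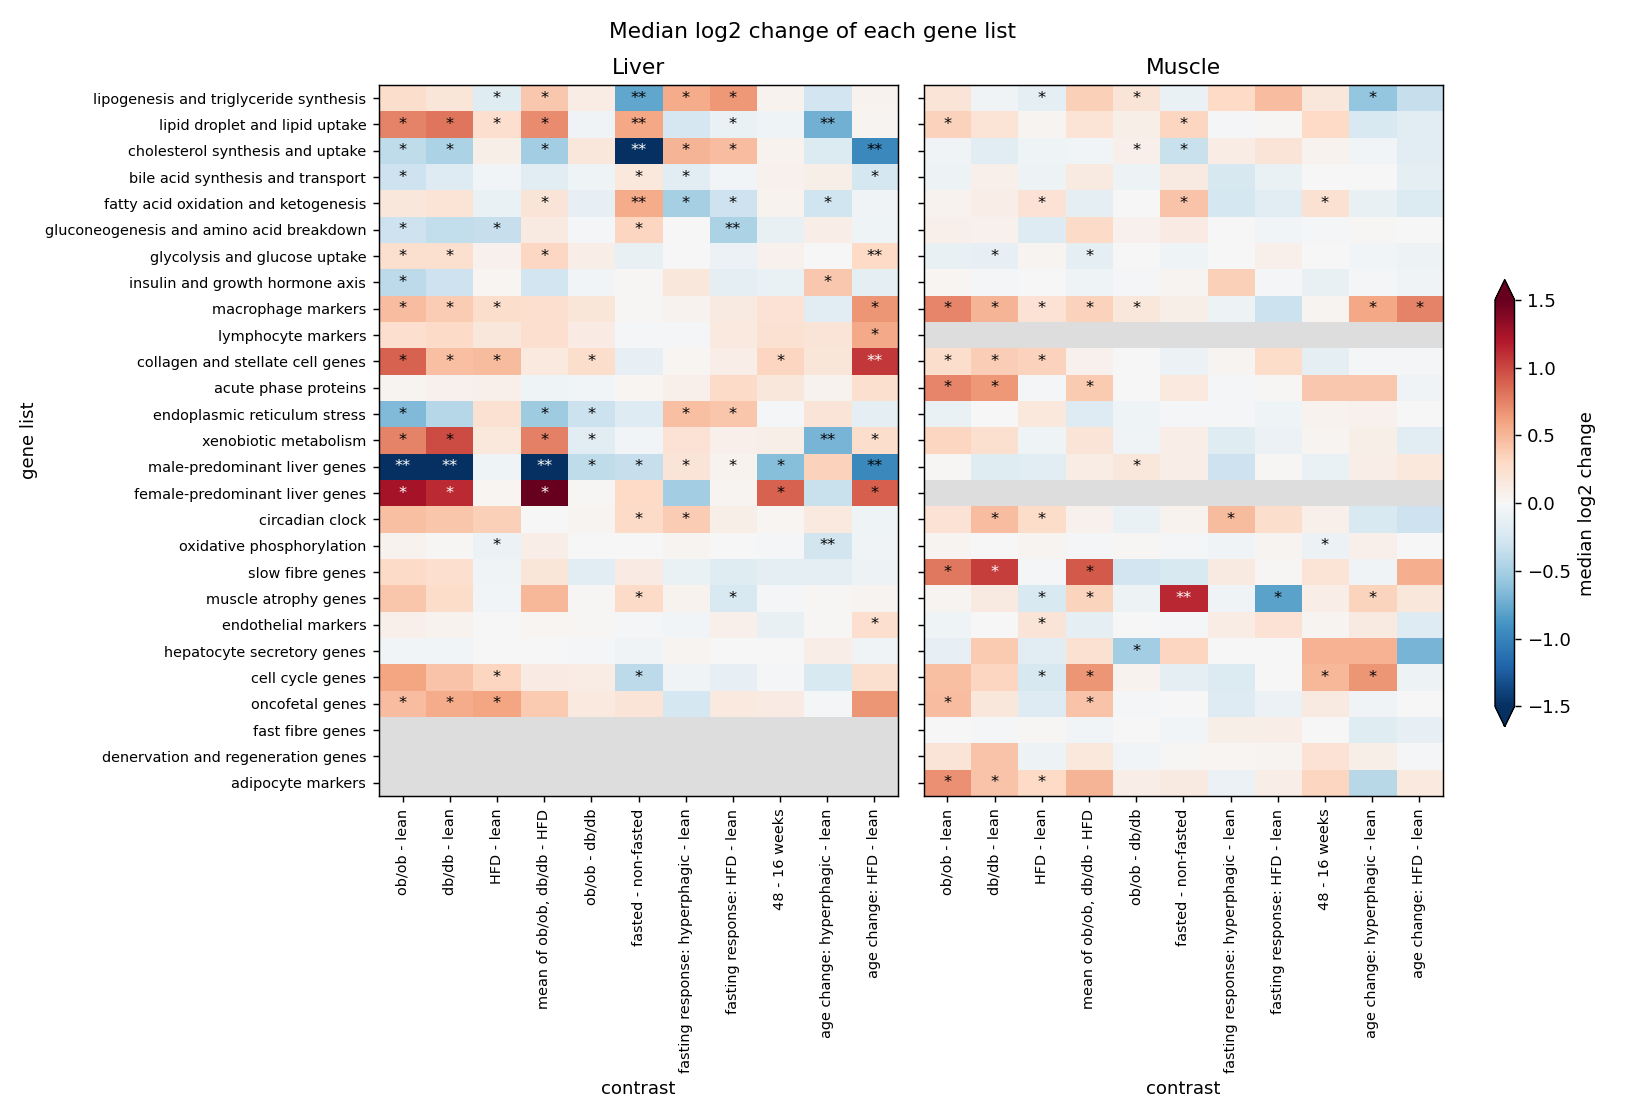
Median log2 change of each gene list (vertical axis) in each comparison (horizontal axis) for liver and muscle, as colour; grey marks lists with under 5 measured members, a star a camera adjusted p under 0.05 and a double star one that also passed with an estimated correlation. Of 539 tests of a list, 135 passed and 16 of these passed with an estimated correlation.

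Muscle of ob/ob mice differed from lean muscle by higher leptin transcripts. Lep rose by 3.64 ± 0.27 (adjusted p = 1.99e-12), and Tph2, Ubd and the imprinted gene Mest were at least 4.51-fold, 4.48-fold and 3.44-fold higher. Of 12 macrophage markers, 10 rose and 0 fell (11 and 0 over the list alone; camera adjusted p = 6.69e-10, adjusted p = 0.215 with an estimated correlation). Lgals3 was at 2.09 ± 0.18 and Trem2, detected on 2 of 12 lean arrays, at least 1.6-fold higher. Of 18 collagen genes, 8 rose and 0 fell (camera adjusted p = 1.78e-05, adjusted p = 0.241 with an estimated correlation). They included Lox (1.32 ± 0.15) and Sparc (0.94 ± 0.10). Of 12 slow fibre genes, 4 rose, Casq2 by 1.09 ± 0.14 and Myoz2 by 0.89 ± 0.21 (camera adjusted p = 0.00196, adjusted p = 0.581 with an estimated correlation). Of 12 acute phase genes 6 rose (camera adjusted p = 0.000798, adjusted p = 0.374 with an estimated correlation), haptoglobin (Hp) by 2.30 ± 0.22. In all 2407 of 8239 genes differed, 1039 higher and 1368 lower; 1412 differed in 16-week mice alone, where Myoz2 (0.66) was not called, and 1328 in 48-week mice alone. Kidney and bone marrow transcripts were also higher (list medians 1.13 and 0.296), the former mainly in non-fasted 16-week ob/ob mice (0.0721 at 48 weeks), the latter between 0.0923 and 0.548 with 1 array left out.

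Adipocyte markers rose in 3 of 7 cases in ob/ob muscle (Adipoq, the adiponectin gene, 1.17 ± 0.19; camera adjusted p = 0.000798, adjusted p = 0.361 with an estimated correlation). At 48 weeks alone Adipoq (0.72) was not called. Fat in the samples stays open as a Lep source in all models, as white fat was not scored. Lipid droplet genes (7 of 17 higher, 1 lower; Plin4 0.74 ± 0.11) and oncofetal genes (3 of 5 higher; Igf2 0.63 ± 0.09) had camera adjusted p of 0.0403 and 0.0491, and adjusted p = 0.656 and 0.215 with an estimated correlation. The genes with the greatest decreases were Mup2 (−3.34 ± 0.44, at least 9.54-fold, detected on 10 of 12 ob/ob arrays), which muscle arrays held together with other liver transcripts, Mup6 (at least 4.33-fold, 4 of 12), Amd2 (−2.00 ± 0.22) and the phosphatase gene Dupd1 (−1.99 ± 0.21). Cish, a target of growth hormone signalling, fell by 1.68 ± 0.22, and Myod1, a myogenic regulator, fell by 0.83 ± 0.13.

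In db/db muscle Lep rose 13.6-fold (3.77 ± 0.27), Tph2, Ubd and Mest were at least 4.79-fold, 3.77-fold and 3.43-fold higher, and Hp rose by 2.21 ± 0.22. Of 12 slow fibre genes, 9 rose and 0 fell (11 and 0 over the list alone; camera adjusted p = 3.27e-06, adjusted p = 0.309 with an estimated correlation; Casq2 1.19 ± 0.14). Of 12 macrophage markers 8 rose (Lgals3 1.83 ± 0.18), of 18 collagen genes 9, of 12 acute phase genes 6 and of 7 adipocyte markers 2, with camera adjusted p of 3.24e-08, 6.83e-07, 9.52e-06 and 0.00202, and adjusted p = 0.213, 0.213, 0.228 and 0.328 with an estimated correlation. Of 12 clock genes 6 rose and 2 fell (Per1 1.10 ± 0.18), and of 14 glycolysis genes 3 fell (Pgam2 −0.31 ± 0.06), at camera adjusted p of 0.0162 and 0.0271, with adjusted p = 0.462 and 0.338 with an estimated correlation. The count of 1544 genes (726 higher, 818 lower) was 3271 with array weights, 2432 without the 7 arrays of wide spread, and 916 and 982 at 16 and 48 weeks alone. At 16 weeks alone Pgam2 (−0.26) was not called.

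On the high-fat diet Lep rose 4.52-fold in muscle (2.18 ± 0.27, adjusted p = 4.15e-06), Ubd was at least 2.31-fold higher and Rab15 rose by 1.35 ± 0.18. Glul, the glutamine synthetase gene, fell by 0.85 ± 0.14, and Fkbp5, a glucocorticoid target, fell by 0.67 ± 0.16. Of 18 collagen genes, 6 rose and 0 fell (9 and 1 over the list alone; camera adjusted p = 8.95e-06, adjusted p = 0.541 with an estimated correlation). Sparc was at 0.53 ± 0.10 and Col4a1 at 0.44 ± 0.08. Of 18 fatty acid oxidation genes 0 passed over all genes and 8 rose and 1 fell over the list alone (camera adjusted p = 0.00199, adjusted p = 0.583 with an estimated correlation). Adipocyte (2 of 7 higher; Car3 0.61 ± 0.15), macrophage (1 of 12, C1qc 0.47 ± 0.11) and atrophy lists (1 of 14 lower, Eif4ebp1 −0.47 ± 0.11) had camera adjusted p of 0.00199, 0.00287 and 0.00199, and an adjusted p = 0.583 each with an estimated correlation. Lipogenesis (1 of 19 higher, Gpam 0.68 ± 0.12), clock, endothelial and cell cycle lists had camera adjusted p of 0.0369, 0.0421, 0.0398 and 0.0369, and adjusted p = 0.792, 0.673, 0.583 and 0.792 with an estimated correlation.

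The count for HFD against lean muscle, 193 genes (140 higher, 53 lower), was 640 with median scaling (614 and 26), 973 with array weights, 607 with only the groups compared, 434 with other-tissue scores as covariates, 350 with runs of 8 numbers as a block and 692 without the arrays of wide spread. With the step at 17 it was 27, without Sparc (0.62), Col4a1 (0.40), Fkbp5 (−0.61), Gpam (0.71), Car3 (0.56), C1qc (0.51) and Eif4ebp1 (−0.49). It was 680 at 16 weeks and 93 at 48 weeks alone, and 107 to 123 without any 1 of 3 arrays. Ubd (0.79), Sparc (0.27) and C1qc (0.18) were not called at 16 weeks alone, nor were Col4a1 (0.26), Glul (−0.69), Fkbp5 (−0.57), Gpam (0.36), Car3 (0.46) and Eif4ebp1 (−0.27) at 48 weeks alone.

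In hyperphagic muscle, set against HFD muscle, the red cell anion exchanger gene Slc4a1 was at least 5.18-fold higher (2.72 ± 0.52, adjusted p = 0.000117; detected on 7 of 12 HFD arrays), and the granulocyte genes S100a9 (2.64 ± 0.64) and Camp (2.36 ± 0.62) were also higher, transcripts that varied within groups with the bone marrow list. Of 12 slow fibre genes 9 rose (camera adjusted p = 0.000254; Casq2 0.98 ± 0.12), of 12 macrophage markers 7 (0.000134; Vsig4 at least 1.69-fold, detected on 2 of 12 HFD arrays), of 14 atrophy genes 7 (0.00255; the cell cycle inhibitor gene Cdkn1a 1.09 ± 0.14) and of 12 acute phase genes 7 (0.00125; Lcn2 2.02 ± 0.38), and 8 of 14 glycolysis genes fell (0.017; Pkm −0.31 ± 0.07). Each of these lists had an adjusted p = 0.356 with an estimated correlation. Cell cycle genes (8 of 12 higher, 1 lower) and oncofetal genes (4 of 5 higher; Igf2 0.66 ± 0.08) had camera adjusted p of 0.00297 and 0.0205, and adjusted p = 0.559 and 0.205 with an estimated correlation. Lep was 2.89-fold higher (1.53 ± 0.23), and Cish was lower (−1.98 ± 0.19). The total was 2954 genes, 1296 higher and 1658 lower (793 and 2748 with median scaling), and 898 in 48-week mice alone, where Lep (0.78), S100a9 (2.14), Camp (2.15) and Pkm (−0.24) were not called. At 16 weeks alone, where these models lie on opposite sides of number 17, there were 2605, without Lcn2 (1.21). The step at 17 left 193, without Lep (0.97), S100a9 (2.46), Camp (2.24), Slc4a1 (2.45), Lcn2 (2.20) and Pkm (−0.23). The changes of Slc4a1 and Lcn2 stayed about as large, and whether the array run adds calls stays open.

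Muscle of ob/ob and db/db mice differed in 3 genes. Itgb3bp was 2.23-fold lower in ob/ob (−1.16 ± 0.10, adjusted p = 1.93e-09) and Cap1 was also lower (−0.82 ± 0.16, adjusted p = 0.02), Pef1 was higher by 0.40 ± 0.07 (adjusted p = 0.00259). Lep differed by −0.13 ± 0.27 (adjusted p = 0.967). Cap1 lies outside the rule for named genes in muscle and was chosen after its values were seen. The macrophage, lipogenesis, cholesterol, male-predominant and hepatocyte secretory lists passed camera with 0 members called (adjusted p = 0.000791, 0.0414, 0.0281, 0.0414 and 0.0414), and had adjusted p = 0.885, 0.896, 0.885, 0.885 and 0.896 with an estimated correlation. The count was 40 with array weights, 70 with other-tissue scores as covariates, 7 without the arrays of wide spread, 16 without replicate 3 of non-fasted 16-week ob/ob mice, 1 with median scaling or with only the groups compared, and 0 by limma in 48-week mice alone (338 at an unadjusted p under 0.05). Cap1 was also not called with median scaling, no filter or only the groups compared. Its call ended (log2 −0.81 to −0.70) without any 1 of 9 arrays. Pef1 was not called with median scaling (0.37) or only the groups compared. At 48 weeks alone Itgb3bp (−0.91), Cap1 (−0.63) and Pef1 (0.33) were not called, nor was Pef1 (0.46) at 16 weeks alone.

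Fasting raised protein breakdown transcripts in muscle. All 14 measured atrophy genes rose (camera adjusted p = 5.59e-18, and 0.00546 with an estimated correlation). The ubiquitin ligase genes Trim63 and Fbxo32 were 3.68-fold (1.88 ± 0.13) and 3.25-fold (1.70 ± 0.09, adjusted p = 1.04e-15) higher, the translation inhibitor gene Eif4ebp1 was at 1.05 ± 0.08 and their regulator Foxo1 at 0.93 ± 0.12. Of 18 fatty acid oxidation genes, 15 rose and 0 fell (camera adjusted p = 2.71e-12, adjusted p = 0.0718 with an estimated correlation). They included Ucp3 (1.61 ± 0.11) and Acot2 (1.68 ± 0.12). Acot1, a thioesterase gene, rose 5.55-fold (2.47 ± 0.17, adjusted p = 9e-14), Depp1 by 2.09 ± 0.16 and the lipoprotein lipase inhibitor gene Angptl4 by 1.81 ± 0.17. Of 16 cholesterol genes 0 rose and 12 fell (camera adjusted p = 1.45e-05, adjusted p = 0.283 with an estimated correlation; Sqle −0.77 ± 0.10), and of 17 lipid droplet genes 9 rose and 1 fell (camera adjusted p = 0.000552, adjusted p = 0.478 with an estimated correlation; Plin5 1.31 ± 0.10). The transferrin receptor gene Tfrc fell by 1.64 ± 0.13. In all 2898 genes differed, 1351 higher and 1547 lower. Lep was at −0.42 ± 0.19 (adjusted p = 0.0777), and was called in 48-week mice alone (−0.77, adjusted p = 0.0212) and (−0.48 to −0.47) without any 1 of 5 arrays.

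The fasting response of muscle differed between HFD and lean mice in Depp1, a target of FoxO factors. It went from 7.95 to 12.00 (16 weeks) and from 7.56 to 11.19 (48 weeks) in lean muscle, and from 8.08 to 8.96 and from 8.56 to 8.67 in HFD muscle, a difference in response of −3.35 ± 0.46 (adjusted p = 9.95e-05). Cdkn1a also had a lower response (−1.57 ± 0.33), and Ky (1.73 ± 0.30), Rgma (1.25 ± 0.20) and Myod1 (1.22 ± 0.26) higher ones. Of 14 atrophy genes, 1 passed over all genes and 7 over the list alone, each with a lower response (camera adjusted p = 1.28e-06, adjusted p = 0.425 with an estimated correlation). Fbxo32 (−0.84 ± 0.27, adjusted p = 0.104) and Trim63 (−1.11 ± 0.36, adjusted p = 0.111) did not pass, but were called with array weights (−0.86 and −1.15), only the groups compared or without the arrays of wide spread. Fbxo32 was also called with median scaling (−1.16) and without replicate 3 of non-fasted 16-week lean mice (−1.01). The call of Cdkn1a ended (−1.55 to −1.41) without any 1 of 5 arrays and that of Myod1 (1.09 to 1.16) without any 1 of 4, replicate 1 of non-fasted 48-week HFD mice among both. Ky, Cdkn1a and Myod1 were called at neither age alone, Depp1 was not called at 16 weeks alone (−3.18) and Rgma was not at 48 weeks alone (0.74). With the step at 17 neither Cdkn1a (−1.56) nor Myod1 (1.15) was called. The count of 35 genes (26 higher, 9 lower; 11 and 75 with median scaling) ranged over the settings tried from 1 in 48-week mice alone and 2 in 16-week mice alone to 1580 with array weights. It was 5 with the step at 17, 111 with other-tissue scores as covariates, 91 with runs of 8 numbers as a block and 1029 without the arrays of wide spread. Leaving out 1 array moved it by more than 1.5 times for 26 of 48 arrays (10 to 140).

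Between hyperphagic and lean muscle, 127 genes had a different fasting response, 94 higher and 33 lower (12 and 94 with median scaling). Depp1 (−1.83 ± 0.40) and Angptl4 (−1.77 ± 0.42) had lower responses, and the heat shock gene Dnajb1 (1.48 ± 0.31, adjusted p = 0.0162) and Gdf10 (1.12 ± 0.22) higher ones. Depp1, Angptl4 and Dnajb1 were called at neither age alone, and Gdf10 was not at 48 weeks alone (0.76). Depp1 (−1.68), Angptl4 (−1.91) and Dnajb1 (1.45) were not with the step at 17, Dnajb1 and Angptl4 were not with only the groups compared, and Angptl4 was not with no filter. The call of Angptl4 also ended (−1.75 to −1.47) without any 1 of 6 lean arrays. The clock list passed with 0 of 12 members called (camera adjusted p = 0.0241, adjusted p = 0.749 with an estimated correlation). The count was 30 at 16 weeks and 0 at 48 weeks alone by limma (689 at an unadjusted p under 0.05 in the latter), 918 with array weights, 65 with no filter and 20 with only the groups compared. It was 42 with the step at 17, 343 with other-tissue scores as covariates, 294 with runs of 8 numbers as a block and 650 without the arrays of wide spread, and moved by more than 1.5 times for 21 of 48 arrays left out (37 to 369).

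**Figure D4:**
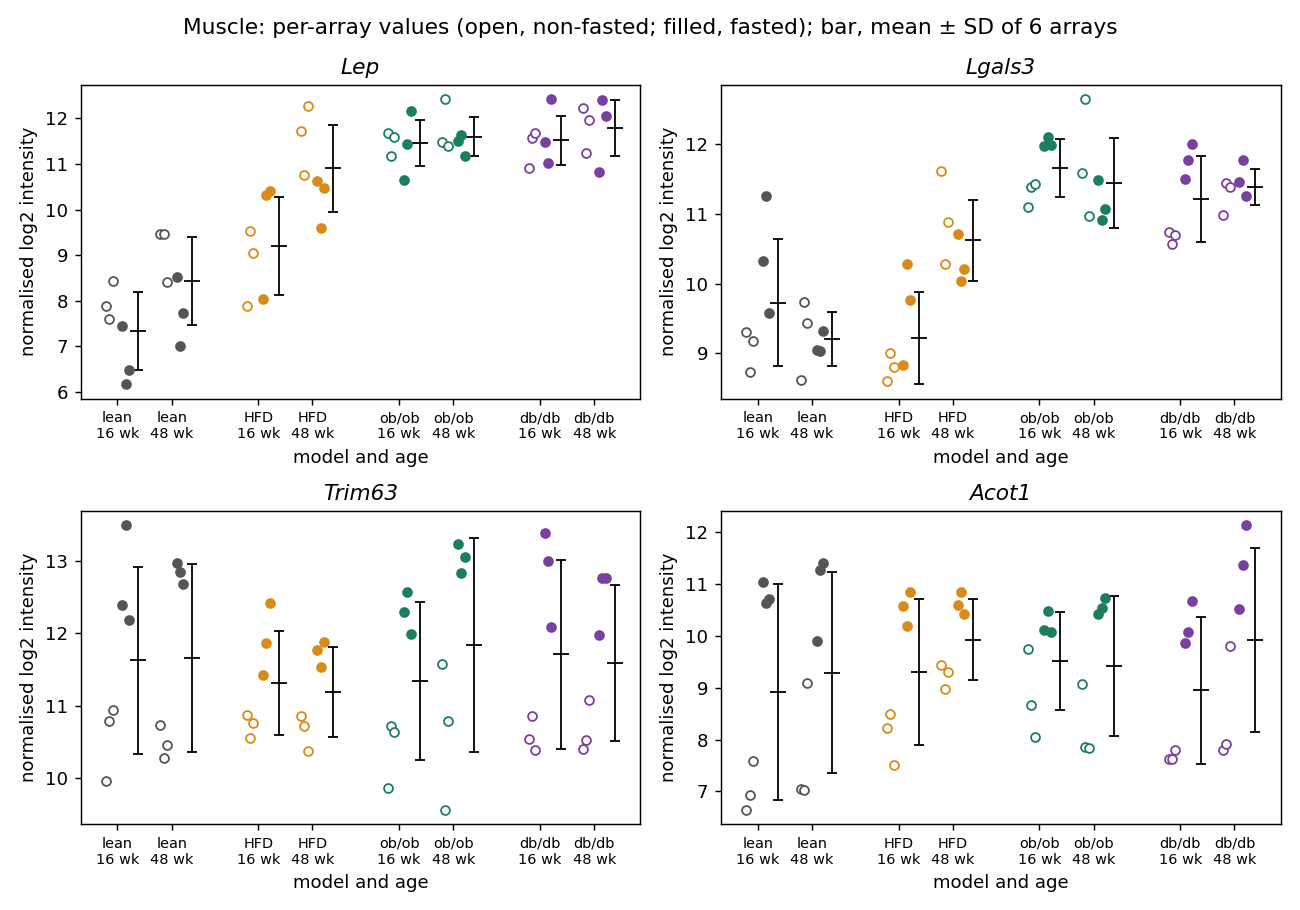
Normalised log2 intensity of Lep, Lgals3, Trim63 and Acot1 on each muscle array by model and age, open circles non-fasted and filled circles fasted, with bars for the mean ± SD of the 6 arrays. Mean Lep was 7.33 and 8.43 in lean muscle at 16 and 48 weeks, and 9.21 and 10.91 in HFD muscle.

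With age, averaged over the models, matrix genes of muscle moved both ways. Col3a1 fell at least 2.31-fold (−1.21 ± 0.12, adjusted p = 7.84e-09), Col1a2 fell by 0.81 ± 0.12 and Kera fell at least 1.63-fold (detected on 5 of 24 arrays at 48 weeks), while Tgfb1 rose by 0.58 ± 0.10 (5 of 24 at 16 weeks). Of 18 collagen genes 3 rose and 8 fell, and the list did not pass (adjusted p = 0.131). The platelet chemokine gene Ppbp rose at least 2.39-fold (detected on 7 of 24 arrays at 16 weeks), Slc7a5 by 1.07 ± 0.13 and Lep by 0.81 ± 0.19 (adjusted p = 0.000999). Of 12 cell cycle genes 9 rose, of 26 oxidative phosphorylation genes 11 fell (Cox7b −0.55 ± 0.11) and of 18 fatty acid oxidation genes 8 rose (Acot2 0.65 ± 0.12), at camera adjusted p of 0.00787, 0.00787 and 0.029, and an adjusted p = 0.954 each with an estimated correlation. The count was 3489, 1830 higher and 1659 lower (2461 and 1189 with median scaling). The change runs across number 17 in all but HFD mice. With the step at 17, limma called 0 genes (406 at an unadjusted p under 0.05), so none of those named, though each kept its sign (Col3a1 −0.28). In HFD mice alone 44 were called (1382 at an unadjusted p under 0.05), among them Col3a1, but not Col1a2 (−0.40), Kera (−0.94), Tgfb1 (0.36), Ppbp (1.01), Slc7a5 (0.39), Lep (1.71) or Acot2 (0.58), and Cox7b turned to 0.08. The design does not separate ageing from the array run outside HFD mice, and the wider error alone can end calls.

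The age response of macrophage markers in muscle was higher in HFD than in lean mice. On the high-fat diet 4 of 12 markers had a higher response (10 over the list alone; camera adjusted p = 1.73e-06, adjusted p = 0.81 with an estimated correlation). Lgals3 was at 1.93 ± 0.36 (adjusted p = 0.0048) and Trem2 at 1.15 ± 0.28. In hyperphagic mice 6 of 12 had a higher response (7 over the list alone; camera adjusted p = 1.08e-05, adjusted p = 0.793 with an estimated correlation). Vsig4 was at 1.12 ± 0.24. Ppargc1b, a coactivator of mitochondrial genes, had a lower response in HFD (−1.28 ± 0.30) and in hyperphagic mice (−1.09 ± 0.26), and Ddit4, an inhibitor of growth signalling, a higher one in hyperphagic mice (2.03 ± 0.51, adjusted p = 0.0199). Without replicate 2 of fasted 16-week lean mice, Ppargc1b (−0.85), Ddit4 (1.67) and Me1 (−0.60) were not called in hyperphagic mice, and Me1 was not with median scaling (−0.53) or only the groups compared. Atrophy (1 of 14 higher), lipogenesis (1 of 19 lower, Me1 −0.68 ± 0.16) and cell cycle lists (0 of 12) passed in hyperphagic mice at camera adjusted p of 0.00306, 0.0462 and 0.00408, with adjusted p = 0.793, 0.97 and 0.811 with an estimated correlation.

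For HFD against lean muscle, 698 genes had a different age response, 239 higher and 459 lower (109 and 1025 with median scaling), and for hyperphagic against lean 401, 164 higher and 237 lower (539 and 49 with median scaling). Leaving out 1 array moved the former by more than 1.5 times for 13 of 48 arrays (256 to 1090), and the latter for 12 (126 to 775). Without the arrays of wide spread they were 2372 and 830, and with other-tissue scores as covariates 1081 and 786. The step at 17 gave 0 by limma (778 at an unadjusted p under 0.05) and 24. Lgals3 (1.99), Trem2 (0.87) and Ppargc1b (−1.47) were then not called in HFD mice, nor Ddit4 (1.74), Me1 (−0.60), Ppargc1b (−1.0) and Vsig4 (1.14) in hyperphagic mice. Runs of 8 sample numbers as a block gave 1570 and 809, array weights 2773 and 1177, only the groups compared 2172 and 108, and no filter 432 for the former.

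Median scaling shifted the median of all genes by over 0.1 in the hyperphagic fasting response (−0.161) and HFD age response (0.136) of liver, and in HFD against lean (0.107), hyperphagic against HFD (−0.113) and the HFD age response (−0.188) of muscle. The SD of log2 changes with the variance of their errors subtracted, over the 7241 genes tested in both tissues, hyperphagic against HFD, was 0.421 in liver and 0.281 in muscle, a ratio of 1.5 (jackknife SE 0.175, or 0.189 with the arrays of 1 sample number left out of both tissues at once, since they may share a mouse), and leaving out each array in turn gave 1.43 to 1.56.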

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

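Tests of other-tissue transcripts, the step within 1 group and the position of 3 muscle genes were chosen after the results they measure were seen. So were the settings added later.

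The tests of a difference in response from lean mice singled out 8 results: 856 genes for hyperphagic and 267 for HFD mice (fasting) and 2272 and 966 (age) in liver, and 127, 35, 401 and 698 in muscle.

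The liver age change outside ob/ob runs mostly across sample number 33, below which all 16-week arrays and all ob/ob arrays lie. Within the fit of all arrays, age called 1956 genes in ob/ob mice, 1980 in db/db, 2849 in lean and 4221 in HFD mice. This cannot tell a run effect from ageing, since number and age go together outside ob/ob. Within the only group on both sides, the step correlated over genes with the age change of lean and HFD mice (0.478). Its correlation with that of ob/ob mice was −0.245, a difference of 0.723. An array run could give this, but it rests on 1 array above the step, the widest in spread (SD 0.305), and genes are not independent. Of 2007 genes called for age in ob/ob mice alone (at most 12 in other splits), 49.4% had the same direction in lean mice. The lean change crosses the step, so a common change stays open. Ageing that differs between models was tested only through the age responses. That of HFD against lean mice called 966 genes (515 with runs of 8 as a block). An equal step cancels there, but signal over background was mostly higher from array 41, where all 48-week HFD and few lean arrays lie. The hyperphagic response crosses the step.

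Muscle arrays differed within groups in transcripts of other tissues. Means of pairwise correlations within groups were 0.864 in the kidney list (8 genes measured), 0.892 in the bone marrow list (13) and 0.887 in the liver list (10), against −0.0477 between lists, but 0.261 in the brown fat list (9), so RNA of other tissues remains open for that list. A lower share of muscle RNA in ob/ob mice would raise all 4 lists, yet the medians of ob/ob minus lean were 1.13, 0.296, −0.121 and −0.143 (kidney, bone marrow, liver, brown fat), the lowest with an SE of 0.126. With 1 array left out they ranged from 0.691 to 1.48, 0.0923 to 0.548, −0.341 to 0.125 and −0.257 to 0.0638. Liver and brown fat took either sign, so a lower share stays open as a cause. The kidney value was carried by non-fasted 16-week ob/ob mice (0.691 without their replicate 1; 2.02 at 16 and 0.0721 at 48 weeks). Mup2 correlated with the liver list over 48 arrays with group means removed (Pearson's r = 0.56, permutation p = 0.00109; Spearman's rho = 0.603, permutation p = 0.0006; r = 0.574 without the 2 farthest arrays), consistent with liver RNA as its source on muscle arrays. In liver Mup2 was itself lower in ob/ob (−4.10 ± 0.37), so its fall in muscle (−3.34 ± 0.44) may carry that of liver.

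The genes that differ between ob/ob and db/db may come from donor chromosome around the mutated genes, which were bred into the same background strain. Among the 40 genes nearest Lep and Lepr, 0 of 17 measured in muscle were called (Fisher's exact test, one-sided, p = 1). This was to exclude a short segment, but with 3 genes called in all only 0.00619 were expected there, so it decides nothing. Nor do 3 of 12 in liver (25%, against 21.1% of the rest; exact p = 0.481). All 3 genes called in muscle, Itgb3bp, Cap1 and Pef1, lie on the same chromosome as Lepr, which holds 6.23% of the others (exact p = 0.000245, which decides nothing, since their position prompted the test), and in each db/db stood apart from ob/ob, lean and HFD (Cap1 means 7.63 in db/db, 6.82, 6.33 and 6.41). In 16-week livers, without those 3 genes, 17 of 99 called genes lie there (17.2% against 5.95%, exact p = 8.64e-05), and in HFD against lean liver the share was 5.03% against 6.41% (p = 0.986). A longer donor segment is consistent with the liver values; a biological effect of the receptor mutation on these genes stays open.

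Chance can be excluded for 19 of the 22 counts by being the highest of 100 splits, so that 1 of 100 was as large. The real counts and the highest others were, in liver, 5650 and 2852 for ob/ob, 4785 and 1968 for db/db, 1691 and 221 for HFD, 5497 and 1372 for hyperphagic against HFD, 1742 and 790 for ob/ob against db/db, 3780 and 642 for fasting, 856 and 1 and 267 and 56 for the fasting responses of hyperphagic and HFD mice, 4711 and 1081 for age, and 2272 and 2 and 966 and 14 for the age responses. In muscle they were 2407 and 753, 1544 and 268, 193 and 10, 2954 and 1475, 2898 and 7 for fasting, 3489 and 445 for age, and 401 and 3 and 698 and 57 for the age responses. For the muscle fasting responses of hyperphagic (127, highest other 280) and HFD mice (35, 281), 2 of 100 splits were as large. For ob/ob against db/db in muscle (3, 794) 11 of 100 were. Chance stays open for these 3, where a split called more genes than the real one, pointing to structure in the samples.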

How the results depend on the processing

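Settings were fixed before the data were examined, except those named above as added after the data were seen. Of 238 counts under settings fixed before, 212 lay within 1.5 times the reported count and 26 moved further; of 100 counts under settings added later, 45 did and 55 moved further. The majority of higher or lower genes turned in 33 cases, with median scaling in 10 of 22 results. Of the genes called for liver age both ways, 179 had the other direction in ob/ob alone and 54 with the step. Among named genes, the age change of liver Col3a1 and Cyp2b9 reversed in ob/ob mice alone (−0.132 and −0.231), as did Lgals3 for HFD against lean liver at 16 weeks alone (−0.0722) and muscle Cox7b for age in HFD mice alone (0.0839). The cause of a move was not tested, except that single ages, ob/ob alone and fits of fewer groups use fewer arrays.

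In liver, the step, estimated from 1 array, gave 592 genes for age, 150 for the hyperphagic age response, 75 for ob/ob against db/db, 3067 for ob/ob against lean and 3512 for hyperphagic against HFD. Runs of 8 sample numbers gave 2892 for age, 515 and 1124 for the HFD and hyperphagic age responses and 896 for ob/ob against db/db, and ob/ob alone gave 2007 for age. The 48-week mice alone gave 2274 for fasting and 21 and 141 for the HFD and hyperphagic fasting responses, and the 16-week mice 99 and 423, 652 for HFD against lean and 101 for ob/ob against db/db. The HFD fasting response was 406 with array weights, 128 with median scaling and 151 with only the groups compared, and the hyperphagic fasting response 1339 with median scaling.

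In muscle, the 16-week mice alone gave 1412 genes for ob/ob and 916 for db/db against lean, 680 for HFD, and 30 and 2 for the hyperphagic and HFD fasting responses. The 48-week mice alone gave 1328, 982 and 93, 898 for hyperphagic against HFD, 0 for ob/ob against db/db and for the hyperphagic fasting response (limma; 338 and 689 at an unadjusted p under 0.05), and 1 for the HFD fasting response. Array weights gave 3271 for db/db and 973 for HFD against lean, 40 for ob/ob against db/db, 918 and 1580 for the hyperphagic and HFD fasting responses and 1177 and 2773 for the age responses. Median scaling gave 640 for HFD against lean, 1 for ob/ob against db/db, 86 for the HFD fasting and 1134 for the HFD age response. With only the groups compared, HFD against lean gave 607, ob/ob against db/db 1, the hyperphagic and HFD fasting responses 20 and 844, and the age responses 108 and 2172.

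In muscle, the step, estimated from 1 array, gave 27 for HFD against lean, 193 for hyperphagic against HFD, 42 and 5 for the hyperphagic and HFD fasting responses, 24 and 0 for the age responses and 0 for age (limma; 778 and 406 at an unadjusted p under 0.05). HFD mice alone gave 44 for age. Other-tissue scores gave 434 for HFD against lean, 70 for ob/ob against db/db, 343 and 111 for the hyperphagic and HFD fasting responses and 786 and 1081 for the age responses. Runs of 8 (negative correlation) gave 350 for HFD against lean, 294 and 91 for fasting and 809 and 1570 for age responses. Without the arrays of wide spread there were 2432 for db/db and 692 for HFD against lean, 7 for ob/ob against db/db, 650 and 1029 for the fasting and 830 and 2372 for the age responses. No filter gave 65 and 23 for the fasting responses and 432 for the HFD age response, and the HFD fasting response was 64 with detection on 24 of 48 arrays and 75 with normexp at an offset of 50.

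Leaving out each array in turn moved a count by more than 1.5 times in 1 liver result, 162 to 322 for the HFD fasting response, and in 6 muscle results. The latter ranged from 107 to 247 for HFD against lean, 2 to 16 for ob/ob against db/db, 37 to 369 and 10 to 140 for the hyperphagic and HFD fasting responses, and 126 to 775 and 256 to 1090 for the age responses.

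Of 135 list calls, 16 held with an estimated correlation, and 132 lists were called without background correction and with the submitters' normalized values.

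The replicate numbers do not pair the samples: arrays of the same number had a median correlation of deviations of −0.00365 in liver (lowest −0.311) and 0.0161 in muscle (lowest −0.598), and 10 of 48 and 18 of 48 arrays correlated best with their own number. The number as a block moved no count by more than 1.5 times.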

Other observations

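The age changes of single models were examined only after other results had been seen.

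Counted within each model, the muscle age change had another pattern than the liver one. It called 2405 genes in ob/ob, 317 in db/db, 2893 in lean and 19 in HFD muscle, whereas the HFD liver had the highest of the liver counts, 4221. HFD muscle arrays all lie above number 17, where signal over background was higher, whereas most other age changes cross it. Array run and age are not separated there, and whether the models differ was tested only through the age responses. In ageing liver the lipid droplet list went both ways, 7 of 17 genes higher and 4 lower, with Cidea at 2.13 ± 0.14. Mean Cidea rose with age in lean (5.54 to 9.87) and HFD livers (5.78 to 11.49) but was lower at 48 weeks in ob/ob (11.79 to 10.85) and db/db livers (11.71 to 11.14). Of 15 macrophage markers 8 rose and 1 fell without the list passing (adjusted p = 0.139; Gpnmb 1.54 ± 0.20).

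In muscle, some transcripts with a role outside of it differed for HFD and for ob/ob against lean. Elane and Prtn3, neutrophil proteases and members of the bone marrow list that varied within groups, were lower in HFD than in lean muscle (−1.39 ± 0.39, adjusted p = 0.0493, and −1.26 ± 0.35), and Cela1, a pancreatic-type elastase gene, was higher in ob/ob muscle (2.63 ± 0.22).

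The 7 muscle arrays of wide spread, with an SD around their group means of 0.331 to 0.453 against a median of 0.234, were replicates of several groups, numbered 1, 4, 10, 11, 26, 32 and 36.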
